A study of Mus musculus with 2 samples.

How the data were processed

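Polyadenylated RNA of mouse embryonic fibroblasts was measured by RNA sequencing in 2 libraries, which the labels number as biological replicates 1 and 2 of 1 group. The labels give each library its own biosample and the same donor or strain record, and no treatment. RNA longer than 200 bases was taken, per the labels, and the labels list spike-ins. For each library the authors deposited tables of genes and of transcripts. Per the text deposited with them, both rest on the mm10 assembly and GENCODE M4 and were counted from alignments to the transcriptome. The column names are those that RSEM writes, but the aligner and the counter are not given in the sources used here. Per the file headers, each table gives the expected count, the estimated number of reads per gene or transcript without normalization. The deposited TPM values are per-million shares of transcripts over all entries, tRNA and spike-in entries included, and the deposited FPKM values are per-million fragments per kilobase. Per the file headers, posterior mean versions of the counts, TPM and FPKM and credibility bounds stand beside them, and the deposited transcript tables give each transcript's percent of its gene's TPM. The effective lengths equal the lengths minus 35 bases, as for 36-base reads, so values of very short genes are scaled up strongly. Whether the counting used strand is not given in the sources used here.

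The tables held 69691 gene-level entries: 43346 Ensembl genes, 26248 tRNA entries and 97 spike-in sequences. Names and positions came from GENCODE M21 on GRCm38, the same assembly, matched on gene ID, and RefSeq annotation of GRCm38.p6 gave overlaps and older symbols. In this way 42462 genes received a name, and 884 had no M21 entry. Replicate 1 held 17360730 expected counts and replicate 2 held 16758143. A level of 0 was given a floor of 3 counts per library, and floors and intervals cover counting error only. tRNA and spike-in entries were left out of library sizes and tests. Levels are the mean and SD of the deposited TPM over 2 libraries, and a gene counted as detected at a TPM of at least 1 in both. The level of a list is the median of its members' mean TPM, and its SD is that of the 2 libraries' own list medians.

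Expected counts were rounded to whole numbers and scaled with TMM factors of 0.971 and 1.03. A biological coefficient of variation was estimated as 1 common dispersion in edgeR over genes kept by its expression filter. The libraries were compared by a two-sided exact binomial test on each gene with a summed count of at least 10, with Benjamini-Hochberg adjustment. A gene differed at an adjusted p under 0.05 and an absolute log2 ratio of at least 1, with a prior count of 2. As the design has 1 library on each side, the test covers counting error and compares those libraries, not conditions. A Pearson and a Spearman correlation of log2(TPM + 1) were taken across genes, and a chi-square over genes asked whether the libraries could be 1 library deposited a second time. The share of a gene's most abundant transcript was computed from TPM for 28 genes with a level of at least 5 TPM, and 2 of them with a single transcript were left out of the counts of genes.

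Before the data were examined, the tests, the main settings, 57 gene lists and the rule for named genes were fixed. The lists covered matrix, cytoskeleton and adhesion, early response and YAP/TEAD targets, cell cycle and p53, secreted factors and interferon, metabolism and stress, Hox clusters and positional factors, imprinting, sex-linked genes, histones, non-coding RNAs, reference and pluripotency genes, and 19 other cell types. Of 843 list members 841 were matched, 26 of them through another symbol, and Rigi and Ahsp were not. Named genes were the 25 with the highest mean TPM, the 4 highest and the lowest member of each list, every member of lists of at most 13, the 10 largest ratios in each direction among named genes that differed at a mean TPM of at least 1, the sex-linked genes and the transcript genes. Others are said to be named after their values were seen. For each list with at least 3 members tested, the median log2 ratio was set among 10000 random lists of the same size matched on deciles of expression, and the median level among 10000 random lists from all genes above 0. These percentiles are descriptions and no p was computed across genes.

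Alternatives, whose effects stand in the closing section, were other detection limits (TPM of at least 0.5 or 0.1, FPKM, 10 counts), posterior means, mitochondrial genes left out, size factors of the RLE kind or total counts, other filters, pseudocounts and prior counts, a 1.5-fold limit, edgeR's exact test with the common dispersion of this pair, and leaving out each replicate. The steps were tested on simulated data drawn from the real means, with 100 genes changed by a log2 ratio of 1.5 and 100 by 3. With counting noise alone, over 16768 genes, the binomial test recovered 100 and 100 with 5 false calls, and edgeR's exact test 96 and 100 with 1. With a dispersion of 0.01, over 16799 genes, the binomial test recovered 97 and 100 with 75 false calls, and edgeR's test 77 and 100 with 1. That dispersion is a coefficient of variation of 0.1, below the 0.196 of this pair, so false calls at the pair's own spread were not simulated. Changes were planted only in genes above a count limit. A simulated coefficient of variation of 0.1 was estimated as 0.100, a planted list stood at percentile 100, and 8 of 100 unchanged lists lay outside the 2.5 to 97.5 range. The lists were checked with counting noise alone and genes drawn independently, so genes that move together were not covered. Tools were R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.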

Results

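Polyadenylated RNA was sequenced from mouse embryonic fibroblasts, primary mesenchymal cells grown out of embryos and widely used as feeder cells and as a starting point for reprogramming. The cells were labelled as male C57BL/6J, and the labelled age of 13.5 weeks, longer than mouse gestation, is given here as labelled. The design held 1 group of 2 biological replicates, each from its own biosample, with no treatment and no second group. The question was therefore which genes these cells carried, at which level, and how far the 2 libraries differed. Replicate 1 held 17360730 expected counts and replicate 2 held 16758143. A count of 0 allowed a level of up to 0.173 CPM (per-million counts) in replicate 1 and 0.179 in replicate 2, from 3 counts of the total, and such limits cover counting error only. Levels are TPM, the per-million share of transcripts, as the mean ± SD of the 2 libraries (SD, n = 2). For a gene list, the level is the median of its members' mean TPM, and the SD is that of the 2 libraries' own list medians. Such a level can lie outside those medians, as for the collagens, at 274 TPM against 266 and 208 in replicates 1 and 2. Positions are on mm10 (GRCm38).

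The most abundant entries of the fibroblast libraries included ribosomal and mitochondrial RNA, small RNA entries and extracellular matrix genes. At a TPM of at least 1 in both libraries, 13615 genes were detected, among them 11562 of 21474 protein-coding genes and 177 long intergenic non-coding RNAs. Another 737 genes reached that level in replicate 1 alone and 1058 in replicate 2 alone, while 18803 of 43346 genes had 0 in both. At least 100 TPM was reached by 1082 genes in both libraries and at least 1000 TPM by 90. The 25 highest genes held 32.7 ± 2.49% of all TPM (SD, n = 2). Only 7 of them were nuclear protein-coding genes, 8 were mitochondrial and 7 were shorter than 200 bases. Protein-coding genes held 64.8 ± 2.37% of TPM and 79.7 ± 0.623% of expected counts. The 37 genes of the mitochondrial chromosome held 10.3 ± 1.19% of TPM and 5.84 ± 0.752% of expected counts. Reads placed on nuclear copies of mitochondrial sequence are not included in these shares.

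Among nuclear protein-coding genes, the elongation factor gene Eef1a1 (chromosome 9, 78478449 to 78489151) was the highest at 10612 ± 170 TPM. It was followed by Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), at 5462 ± 583 TPM and by the cytoplasmic actin gene Actb at 5328 ± 1359 TPM. Lars2, the mitochondrial leucyl-tRNA synthetase, stood at 4630 ± 73.0 TPM, the proteoglycan gene Bgn at 4094 ± 429, fibronectin (Fn1) at 3980 ± 1400 and the matrix glycoprotein Sparc at 3728 ± 353. The nuclear non-coding RNA Malat1 reached 4149 ± 311 TPM. The highest entry of all, ENSMUSG00000045999.9, at 70071 ± 2421 TPM, had no name or position in the annotation used here, nor had ENSMUSG00000089855.1 at 7562 ± 2011 TPM. Gm42418 (chromosome 17, 39846958 to 39848788), at 57344 ± 5453 TPM, lay entirely inside an annotated ribosomal RNA gene. The miRNA entry Mir6236 reached 41428 ± 11992 TPM. Whether the reads counted for Lars2 and for Mir6236 came from those genes themselves was not settled here. Mitochondrial entries in the 25 were mt-Rnr1 and mt-Rnr2, the ribosomal RNAs, at 14444 ± 2005 and 10284 ± 3418 TPM, the tRNA mt-Ts1 at 11881 ± 3068 TPM, and mt-Co1, mt-Co2, mt-Co3, mt-Atp8 and mt-Cytb at 5141 to 12993 TPM. The TPM of mt-Ts1 is scaled up strongly, as this entry is 69 bases long and held 3872 and 5566 counts in replicates 1 and 2. It overlaps mt-Co1 by 3 bases, and whether its reads came from the tRNA itself was not settled here. Some values were uncertain because reads cannot be placed: Gm10925, at 6023 ± 269 TPM, is a nuclear copy of mitochondrial sequence, mt-Co2 and mt-Co3 share nearly all their sequence with nuclear copies, and the pseudogene Rpl39-ps, at 3537 ± 479 TPM, resembles Rpl39. Snord14d and Snord14c, at 9416 ± 1273 and 6446 ± 1100 TPM, lay within Hspa8, and Gm27786, at 4590 ± 2783 TPM, lay within H19. Whether the counting used strand was not stated, so it is not known whether overlapping and antisense genes were told apart.

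The 2 libraries shared most of their expression profile, yet differed by more than counting error. Across 43346 genes, log2(TPM + 1) correlated between them with a Pearson r of 0.985 and a Spearman rho of 0.917, and genes are not independent replicates. Of 14550 genes with a mean TPM of at least 1, 82.8% lay within 1.5-fold, and the median absolute log2 ratio was 0.22. The common biological coefficient of variation was 0.196 over 14263 genes. A chi-square of counts over genes was 36.6 times its 16730 degrees of freedom, so the libraries were not 1 library deposited a second time. In an exact binomial test that covers counting error, 1160 of 16731 genes differed at least 2-fold, 745 higher and 415 lower in replicate 2, and 5792 had an adjusted p under 0.05 before the 2-fold rule. This test compared the 2 libraries, not conditions, and it had no replicate check. With the spread of the pair itself as the error, in edgeR's exact test, 357 genes passed, and with ratios of TPM + 1 the count was 590. That spread came from the same 2 libraries, as 1 value for all genes, so edgeR's test had no replicate check either. The spread varied with the genes used, at 0.225 without a filter and 0.181 at a mean TPM of at least 10. A single value may be too small for genes with few counts. Below, a gene is called higher, lower or different only where it passed both the binomial test and the 2-fold rule, so genes not called may still differ by less. For all 57 fixed gene lists, the counts adjusted over the list alone were the same as those over all genes.

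**Figure D1:**
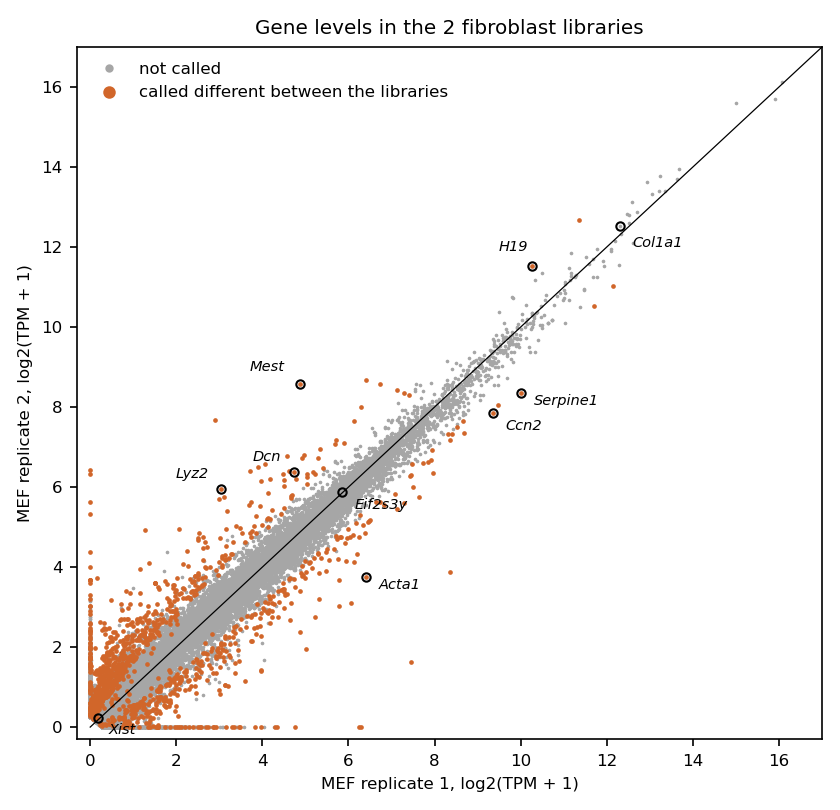
Each point is a gene, with its level in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis, both as log2(TPM + 1), and orange points are the 1160 genes that passed the exact test and the 2-fold rule between the libraries. Col1a1 (5049 and 5874 TPM) and Eif2s3y lie close to the diagonal, Mest and Lyz2 lie above it and Serpine1 and Acta1 below it.

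Fibroblast identity genes were all detected, and matrix genes were among the most abundant transcripts. All 18 fibroblast and mesenchymal genes were detected at a median of 70.4 ± 16.5 TPM (median log2 ratio of replicate 2 over 1 of 0.12, percentile 99.7 of random lists), led by the intermediate filament gene Vim at 2415 ± 613 TPM, S100a4 at 488 ± 314, the surface glycoprotein Thy1 at 457 ± 118 and the mesenchymal transcription factor Prrx1 at 336 ± 48.8. Fap, a fibroblast protease, was the lowest at 20.4 ± 8.48 TPM. In this list 2 genes were higher and 2 lower in replicate 2. They were Lum and Dcn (log2 ratios 2.54 and 1.64), and S100a4 and Cd44 (-1.46 and -1.27). All but Cd44 passed edgeR's exact test, and Lum and Dcn were named after their values were seen. All 19 collagens were detected at a median of 274 ± 41.2 TPM (0.10, percentile 99.8), with Col1a2 at 2536 ± 418, Col3a1 at 1799 ± 733 and Col12a1 at 768 ± 75.3 TPM. Col14a1 was higher in replicate 2 (log2 ratio 2.25) and Col2a1, the cartilage collagen, lower (21.7 and 9.44 TPM in replicates 1 and 2), and of these 2 only Col14a1 passed edgeR's test. All 24 matrix glycoproteins and proteoglycans were detected, at a median of 185 ± 25 TPM (0.07, percentile 99.5), with Nid2 lowest at 34.8 ± 12.2. Their log2 ratios were above 0 in 12 and below 0 in 12. Summed TPM was 21692 in replicate 1 and 18363 in replicate 2, so the list was not raised as a whole. Of these 24 genes, 5 were higher and 1 was lower in replicate 2. The higher ones were Lum and Dcn with Mfap4, Fbn2 and the elastin gene Eln (log2 ratios 1.81, 1.36 and 1.83, named after their values were seen), and the lower one was thrombospondin 1, Thbs1 (3314 and 1467 TPM in replicates 1 and 2), the only one of the 6 that did not pass edgeR's test. The 14 collagen processing genes, such as the collagen chaperone Serpinh1 at 1163 ± 160 TPM, were all detected at a median of 93.3 ± 5.91 TPM (-0.06, percentile 57.3), and none differed.

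Contractile genes, targets of the mechanically regulated YAP/TEAD factors and early response genes were on the lower side in replicate 2. All 19 contractile and smooth muscle genes tested had a log2 ratio below 0, with a median of -0.53 against random lists of the same size and level (percentile 0). Smooth muscle actin, Acta2 (chromosome 19, 34241090 to 34255590), stood at 2836 ± 592 TPM, Tpm1 at 1935 ± 439, Cald1 at 1228 ± 309 and Flna at 1102 ± 164. Of that list, 18 members were detected, Myocd at 0.730 ± 0.226 TPM was not, and only Cnn1, named after its values were seen, was lower by the 2-fold rule. All 10 YAP/TEAD target genes were detected, their median log2 ratio was -0.62 (percentile 0), and 3 were lower. These were Ccn2 (chromosome 10, 24595442 to 24598683; 652 against 229 TPM), Ankrd1 (60.8 against 16.7) and Crim1 (54.4 against 26.0), and 2 of the 3 passed edgeR's exact test. The others included Axl at 321 ± 133, Ccn1 at 319 ± 118 and Tead1 at 180 ± 21.3 TPM. Of 21 immediate early genes 20 were detected, led by Fosl2 at 86.6 ± 0.191 TPM and Btg2 at 57.6 ± 12.2, with a median log2 ratio of -0.34 (percentile 0.02) and 1 gene lower, Fosl1 (log2 ratio -1.40, named after its values were seen). Of 18 integrins 14 were detected, led by Itgb1 at 1082 ± 370 TPM, with a median log2 ratio of -0.41 (percentile 0) and 2 genes lower, Itga5 (172 against 76.0 TPM) and, named after its values were seen, Itga3. Of 21 matrix proteases and inhibitors 19 were detected. Serpine1, the plasminogen activator inhibitor, was lower (chromosome 5, 137061504 to 137072268; 1032 against 328 TPM), as was Plau, named after its values were seen. That list's median log2 ratio was -0.16 (percentile 8.37). By edgeR's exact test 0 of the contractile, immediate early and integrin genes and 1 of the proteases and inhibitors passed.

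Cadherin and intermediate filament genes were detected in part. Among 9 cadherins, 6 were detected, Cdh11 at 276 ± 90.3 TPM Cdh2, N-cadherin, at 42.9 ± 8.04 and Cdh3, P-cadherin, at 34.3 ± 7.24, whereas epithelial Cdh1, E-cadherin, was at 0.01 ± 0.0141 TPM. None differed, and their median log2 ratio of 0.29 (percentile 98.3) became 0.06 (percentile 70.1) with ratios of TPM + 1. Of 15 intermediate filament genes 7 were detected, with Lmna at 306 ± 14.6 and Lmnb1 at 34.7 ± 10.1 TPM, and Krt5 at 0 in both libraries. In this list Nes, Krt18 and Krt19 were lower and Gfap, named after its values were seen, higher in replicate 2, at a list median log2 ratio of -0.11 (percentile 19.7), which was -0.44 and outside the range of random lists over members with a mean TPM of at least 1. Of the 4, Krt19 did not pass edgeR's exact test.

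Mitotic genes stood higher as a group in replicate 2, and p53 targets lower. All 18 G2/M and mitosis genes were detected, with log2 ratios above 0 in every case, a median of 0.48 (percentile 100) and no single gene past the 2-fold rule. Cdk1, the mitotic kinase, was at 114 ± 15.2 TPM, Top2a at 93.3 ± 28.2, Ccna2 at 67.5 ± 18.8 and Ube2c at 64.0 ± 14.5. All 21 G1/S and replication genes were detected, with a median log2 ratio of 0.16 (percentile 99.9) and none different, among them Ccnd2 at 319 ± 81.3, Ccnd1 at 135 ± 54.6 and Pcna at 125 ± 24.2 TPM. The 18 p53 target genes had a median log2 ratio of -0.41 (percentile 0). Cdkn1a, which encodes p21, was at 335 ± 106 TPM, Ccng1 at 275 ± 80.7 and Mdm2 at 146 ± 65.5, and only Perp, named after its values were seen, was lower, though not by edgeR's exact test. All 16 cell cycle inhibitor and senescence-associated genes were detected, with a median log2 ratio of -0.22 (percentile 1.44), which was -0.17 and inside the range of random lists with ratios of TPM + 1. Of these, 2 were higher (Cdkn1c and Igfbp3, log2 ratios 2.73 and 2.24) and 3 lower (Serpine1, Igfbp7 and Cdkn2a, the last at -1.09), and Cdkn1c and Igfbp3 were named after their values were seen. By edgeR's exact test 3 of the 5 passed, and Igfbp7 and Cdkn2a did not. Il6 was the lowest of them at 1.86 ± 0.912 TPM. Of 19 replication-dependent histone genes 15 were detected, at a median of 4.18 ± 1.41 TPM and a median log2 ratio of 0.47 (percentile 98.2). There, 4 linker histone genes, Hist1h1a, Hist1h1b, Hist1h1d and Hist1h1e, were higher by the binomial test and 0 of these by edgeR's exact test, and all were named after their values were seen. All 8 polyadenylated histone variant genes were detected, led by H3f3a at 457 ± 104 and H3f3b at 252 ± 65.0 TPM, with a median log2 ratio of 0.46 (percentile 100) and none different. Histone genes have near-identical copies, so their values are uncertain. The libraries were of polyadenylated RNA, so replication-dependent histone RNA without a poly(A) tail was not selected for, and these levels need not follow its amount.

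Imprinted genes were abundant and leaned to replicate 2. Of 28 imprinted genes, 25 were detected at a median of 44.6 ± 10.8 TPM, with a median log2 ratio of 0.19 (percentile 100), 6 higher and none lower. The non-coding RNA H19 (chromosome 7, 142575529 to 142578143) was higher, at 1226 and 2969 TPM in replicates 1 and 2. Its neighbour Igf2, a fetal growth factor gene, stood at 1447 and 2612 TPM, a log2 ratio of 0.99. Mest (chromosome 6, 30723547 to 30748465) was at 28.4 and 381 TPM, a log2 ratio of 3.78. Cdkn1c, Plagl1, Peg3 and Zim1 were also higher (log2 ratios 2.73, 1.94, 1.20 and 1.13), and with Mest they were named after their values were seen. By edgeR's exact test 3 of the 6 passed. Rian at 983 ± 28.1 TPM and Grb10 at 651 ± 44.3 did not differ, and Phlda2 was at 0 in both libraries.

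Secreted factors went both ways. Of 31 growth factors and secreted antagonists 28 were detected, with 3 higher and 5 lower in replicate 2, 3 of them by edgeR's exact test, and a median log2 ratio of -0.05 (percentile 43.5). The 3 higher were Sfrp2 (1.41 and 29.5 TPM), Igf1 (6.90 and 51.1 TPM) and Sfrp1, and the 5 lower were the activin subunits Inhba and Inhbb, their antagonist Fst, Fgf2 and Ngf. All 8 were named after their values were seen. Grem1, a BMP antagonist, was at 226 ± 95.2 TPM and Tgfb3 at 132 ± 5.15. Of 18 cytokines and chemokines 14 were detected, with Cxcl12 at 294 ± 42.5, Csf1 at 186 ± 43.5 and Ccl7 at 99.9 ± 0.417 TPM, and Il1b at 0 in both. Cxcl5 and Il33 were higher and Il11 lower, all 3 named after their values were seen and 1 of them past edgeR's test, at a list median log2 ratio of -0.05 (percentile 32.8), or -0.20 and outside the random range with ratios of TPM + 1. Of 19 interferon-stimulated genes 16 were detected, led by Ifi27 at 116 ± 3.93 TPM and Bst2 at 54.6 ± 0.0919. Their median log2 ratio was 0.19 (percentile 96.9), and Mx1, named after its values were seen, was higher, though not by edgeR's exact test.

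Metabolic and housekeeping genes were mostly detected, and none differed by the 2-fold rule. All 16 glycolysis genes had log2 ratios below 0, with a median of -0.45 (percentile 0) and none past the 2-fold rule, among them Eno1 at 855 ± 195, Ldha at 552 ± 84.3 and Pkm at 508 ± 133 TPM. All 21 cholesterol synthesis genes were detected, with a median log2 ratio of -0.32 (percentile 0.02) and none different, and Hmgcr, the rate-limiting enzyme, stood at 96.7 ± 13.8 TPM. All 13 hypoxia response genes (median log2 ratio -0.16, percentile 8.73; P4ha1 at 115 ± 11.3 TPM), all 18 unfolded protein and amino acid response genes (-0.02, percentile 76.6; Hspa5 at 771 ± 80.8 TPM) and all 17 nuclear respiratory chain genes (-0.14, percentile 11.7; Atp5b at 598 ± 74.4 TPM) were detected, and no member differed. The same held for 24 cytosolic ribosomal protein genes at a median of 788 ± 1.22 TPM (-0.10, percentile 37.6), 13 mitochondrially encoded protein genes at 3059 ± 179 TPM (-0.02, percentile 82.5) and 18 reference genes at 343 ± 57.6 TPM (-0.10, percentile 34.6). Of 10 nuclear non-coding RNAs 8 were detected and none differed (median log2 ratio 0.11, percentile 93.7, and 0.27 and outside the random range over members with a mean TPM of at least 1), among them Meg3 at 553 ± 20.8, Rn7sk at 456 ± 134 and Neat1 at 160 ± 22.6 TPM.

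Positional genes of trunk and limb were present, and the Hox clusters differed in the direction of their median log2 ratio. All 11 HoxA genes were detected, with Hoxa7 at 10.2 ± 3.25 and Hoxa10 at 8.16 ± 2.33 TPM, and their median log2 ratio was -0.41 (percentile 0.29). Of 10 HoxB genes 8 were detected, all with log2 ratios below 0 (median -0.62, percentile 0), with Hoxb9 (chromosome 11, 96271457 to 96276595) at 24.3 ± 3.66 TPM and Hoxb1 and Hoxb13 at 0. Of 9 HoxC genes 6 were detected, Hoxc6 at 30.4 ± 9.62 and Hoxc8 at 20.2 ± 6.39 TPM, and Hoxc10 was higher in replicate 2 (3.81 and 8.45 TPM), though not by edgeR's exact test, at a list median of -0.07 (percentile 29.1), or -0.32 and outside the random range over members with a mean TPM of at least 1. Of 9 HoxD genes 8 were detected, with Hoxd13, a gene of the distal limb, at 9.66 ± 0.856 TPM and a median log2 ratio of 0.54 (percentile 98.9). With ratios of TPM + 1 the HoxD median was 0.27 and inside the range of random lists. No HoxA, HoxB or HoxD gene differed by the 2-fold rule. The median TPM of a cluster went against its log2 ratio for HoxA (2.48 and 4.24 in replicates 1 and 2), HoxC (3.81 and 5.92) and HoxD (2.26 and 2.01). That of HoxB, and the summed TPM of every cluster, went with it. The direction of a cluster is thus uncertain at these low levels. Of 36 limb, body wall and craniofacial transcription factors 25 were detected, led by Pbx1 at 72.6 ± 0.509, Tbx15 at 57.8 ± 12.1, Meis2 at 51.7 ± 6.76 and Shox2 at 25.2 ± 8.88 TPM, and Otx2 was at 0. Their median log2 ratio was 0.48 (percentile 100), with 7 higher, 1 lower and 5 of the 8 past edgeR's exact test. The hindlimb factors Pitx1 and Tbx4 (log2 ratios 2.37 and 1.93), Wt1, Barx1, Msx1, Alx4 and Lmx1b were higher and the forebrain factor Foxg1 was lower (-1.80), and all but Wt1 were named after their values were seen.

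**Figure D2:**
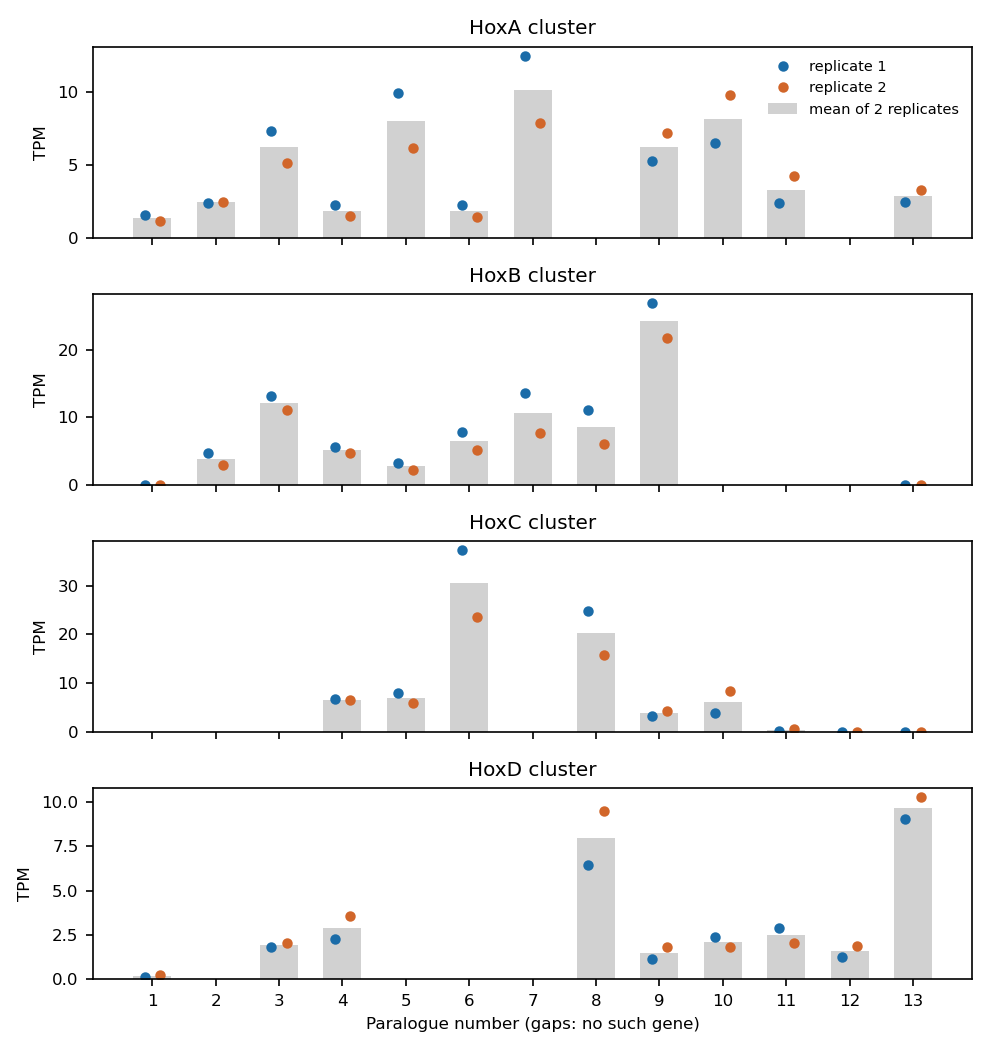
Bars give the mean TPM of the 2 replicates for each Hox gene by paralogue number, and points give each replicate. Hoxc6 (30.4 ± 9.62 TPM) and Hoxb9 (24.3 ± 3.66 TPM) were the highest, and Hoxb1, Hoxb13 and Hoxc12 were at 0.

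Markers of other cell types were mostly low, with macrophage and leukocyte genes higher in replicate 2. Over 19 such lists, 50 of 208 members were detected in both libraries. Of 12 macrophage markers 2 were detected in both, 9 were higher in replicate 2 and 8 of these also by edgeR's exact test, at a median log2 ratio of 2.58 (percentile 100). Lyz2, which encodes lysozyme (chromosome 10, 117277331 to 117282321), was at 7.27 and 61.3 TPM, the complement genes C1qa, C1qb and C1qc at 0.250, 0.810 and 0.730 in replicate 1 against 4.53, 5.46 and 5.51 in replicate 2, and Adgre1, which encodes F4/80, at 0.3 and 1.71. Taken by itself, replicate 2 had 10 of the 12 at 1 TPM or more, the 2 detected in both among them. Of 10 leukocyte markers 1 was detected in both and 9 were higher, 5 of them by edgeR's test, at a median log2 ratio of 2.38 (percentile 100). They included Laptm5 (0.4 and 8.01 TPM), Lcp1 (0.850 and 6.83) and Ptprc, which encodes CD45 (0.450 and 1.06). Of the 10 leukocyte markers, 8 reached 1 TPM in replicate 2 taken by itself, the 1 detected in both among them. None of 11 erythroid markers was detected, and adult haemoglobin genes such as Hbb-bs and Hba-a1 had 0 counts.

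**Figure D3:**
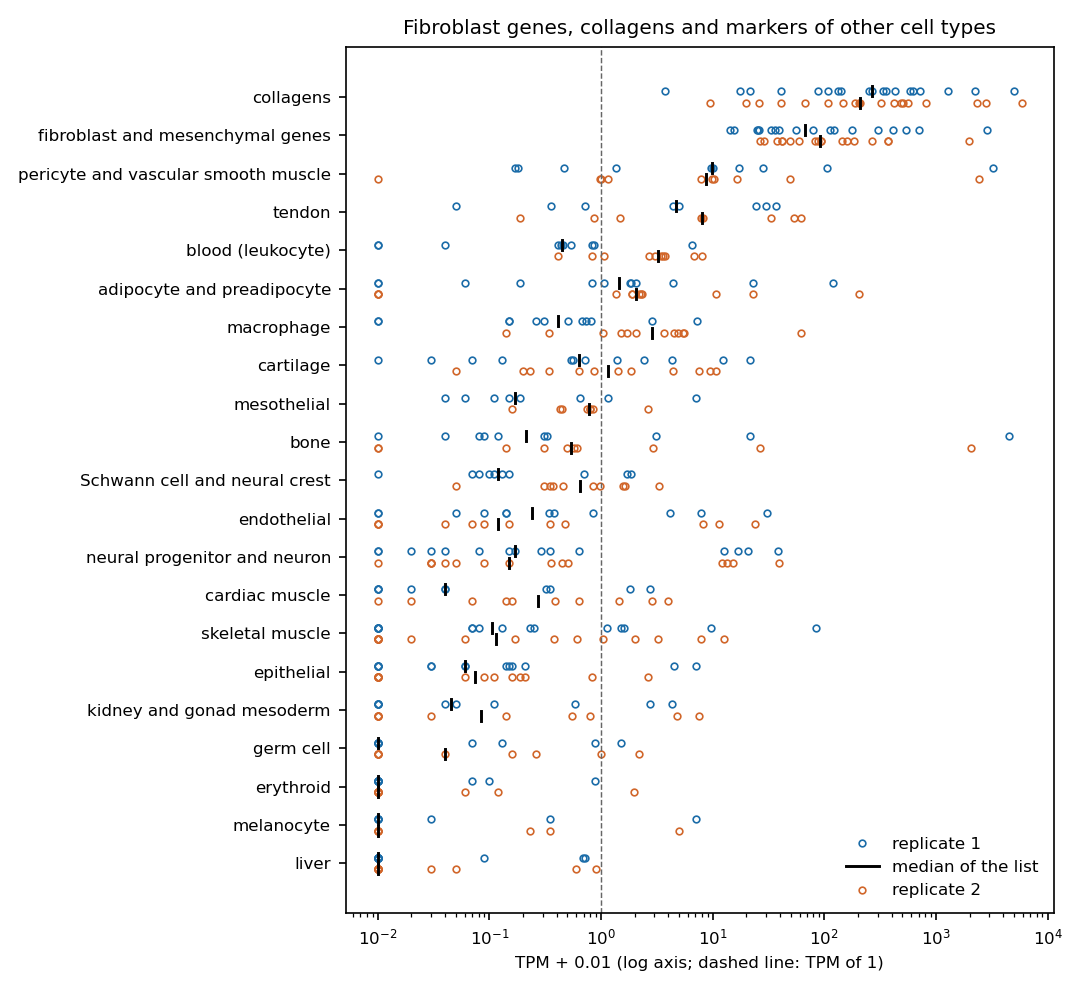
Each point is a gene of a fixed list in replicate 1 (blue) or replicate 2 (orange), on a log axis of TPM + 0.01, and black ticks are list medians per replicate. The medians of collagens (266 and 208 TPM in replicates 1 and 2) and fibroblast genes (67.4 and 90.8 TPM) lie above those of the other cell type lists. Macrophage and leukocyte medians lie higher in replicate 2.

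Some markers of other mesenchymal lineages were detected. Of 10 pericyte and vascular smooth muscle markers 6 were detected (median log2 ratio -0.47, percentile 0.14), with Mcam lower (105 against 48.8 TPM) and Abcc9 and Kcnj8 higher, and of 12 adipocyte and preadipocyte markers 7 (0.73, percentile 99.9), with Dlk1, a preadipocyte factor, at 162 ± 58.8 TPM and Lpl, Zfp423, Cebpa and Cd36 higher. Of 8 tendon markers 5 were detected (0.80, percentile 99.97), with Fmod at 45.7 ± 22.5 TPM and Tnmd (24.3 and 53.3 TPM) and Thbs4 higher. Of 12 cartilage markers 5 were detected (0.50, percentile 98.9, and 0.25 and inside the random range with ratios of TPM + 1), with Col2a1 lower and Sox6 and Col9a1 higher. Of 10 bone markers 3 were detected, and Spp1, osteopontin, was lower (chromosome 5, 104435118 to 104441050; 4521 against 2082 TPM). The bone median of 0.63 (percentile 98.4) turned to -0.17 over members with a mean TPM of at least 1. Of 16 skeletal muscle markers 5 were detected (0.16, percentile 65.8, and -0.20 over members with a mean TPM of at least 1), with Acta1 lower (83.9 against 12.5 TPM) and Pax3 higher, and of 10 cardiac markers 2 (0.98, percentile 96.8), with Myh6 higher. Of 10 Schwann cell and neural crest markers 1 was detected (1.92, percentile 100), and Ngfr, Cdh19, Sox10, Erbb3 and Plp1 were higher, 2 of the 5 by edgeR's test. Of 8 mesothelial markers 1 was detected (1.62, percentile 99.96), with Krt19 lower and Upk3b, Wt1, Gpm6a and Lrrn4 higher, 1 of these 5 by edgeR's test. Of 10 kidney and gonad mesoderm markers 2 were detected (0.74, percentile 96.4, and 0.65 and outside the random range with ratios of TPM + 1), with Wt1 higher. By edgeR's exact test 1 of the adipocyte and 1 of the skeletal muscle calls passed, and 0 of the pericyte, tendon, cartilage, bone, cardiac, and kidney and gonad calls.

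Among the remaining lists, 3 of 12 endothelial markers were detected, Flt1 at 27.1 ± 4.73, Egfl7 at 8.02 ± 0.170 and Erg at 7.75 ± 5.05 TPM, while Cdh5 and Pecam1 stayed below 0.1 TPM (median log2 ratio -0.08, percentile 25.3), with Erg and Tek higher and Emcn lower, none of them by edgeR's exact test. Of 14 epithelial markers only Krt19, at 4.87 ± 3.21 TPM, was detected (-0.91, percentile 0.86), and Krt19 and Krt18 were lower, 1 of them by edgeR's test. Of 15 neural markers 4 were detected (0.11, percentile 69.4, and -0.24 over members with a mean TPM of at least 1), with Map2 higher (20.6 and 39.4 TPM), Nes lower, 1 of these by edgeR's test, and Tubb3 at 14.5 ± 3.44. Of 7 melanocyte markers only Mitf, at 6.03 ± 1.49 TPM, was detected, of 9 germ cell markers only Prdm1, at 1.84 ± 0.481 TPM (0.17, percentile 55.3), and of 12 liver markers none, and no member of these 3 lists differed. Of 14 pluripotency and reprogramming genes 2 were detected, Myc at 41.2 ± 10.9 and Klf4 at 32.2 ± 7.27 TPM, while Sox2 was at 0.390 ± 0.156, Nanog at 0.530 ± 0.0849 and Lin28a at 0 (median log2 ratio -0.22, percentile 13.4). Among random lists of all genes above 0 TPM, the median levels of the collagens and of the fibroblast genes stood at percentile 100. That of the pluripotency list stood at percentile 0. The melanocyte, liver and erythroid lists had a median of 0 TPM, so their percentile of 0 was fixed by drawing only genes above 0. In all, 31 of 53 lists tested had a median outside the central 95% of random lists, 19 higher and 12 lower in replicate 2, where chance gives 2.65. Higher and lower are here against random lists, whose range lay mostly below 0 for abundant lists. For matrix glycoproteins and proteoglycans, counted as higher, it ran from -0.19 to 0.03, against a median of 0.07. That list had 12 members above 0 and 12 below. Genes move together and lists share members, so these percentiles only describe the pair of libraries.

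**Figure D4:**
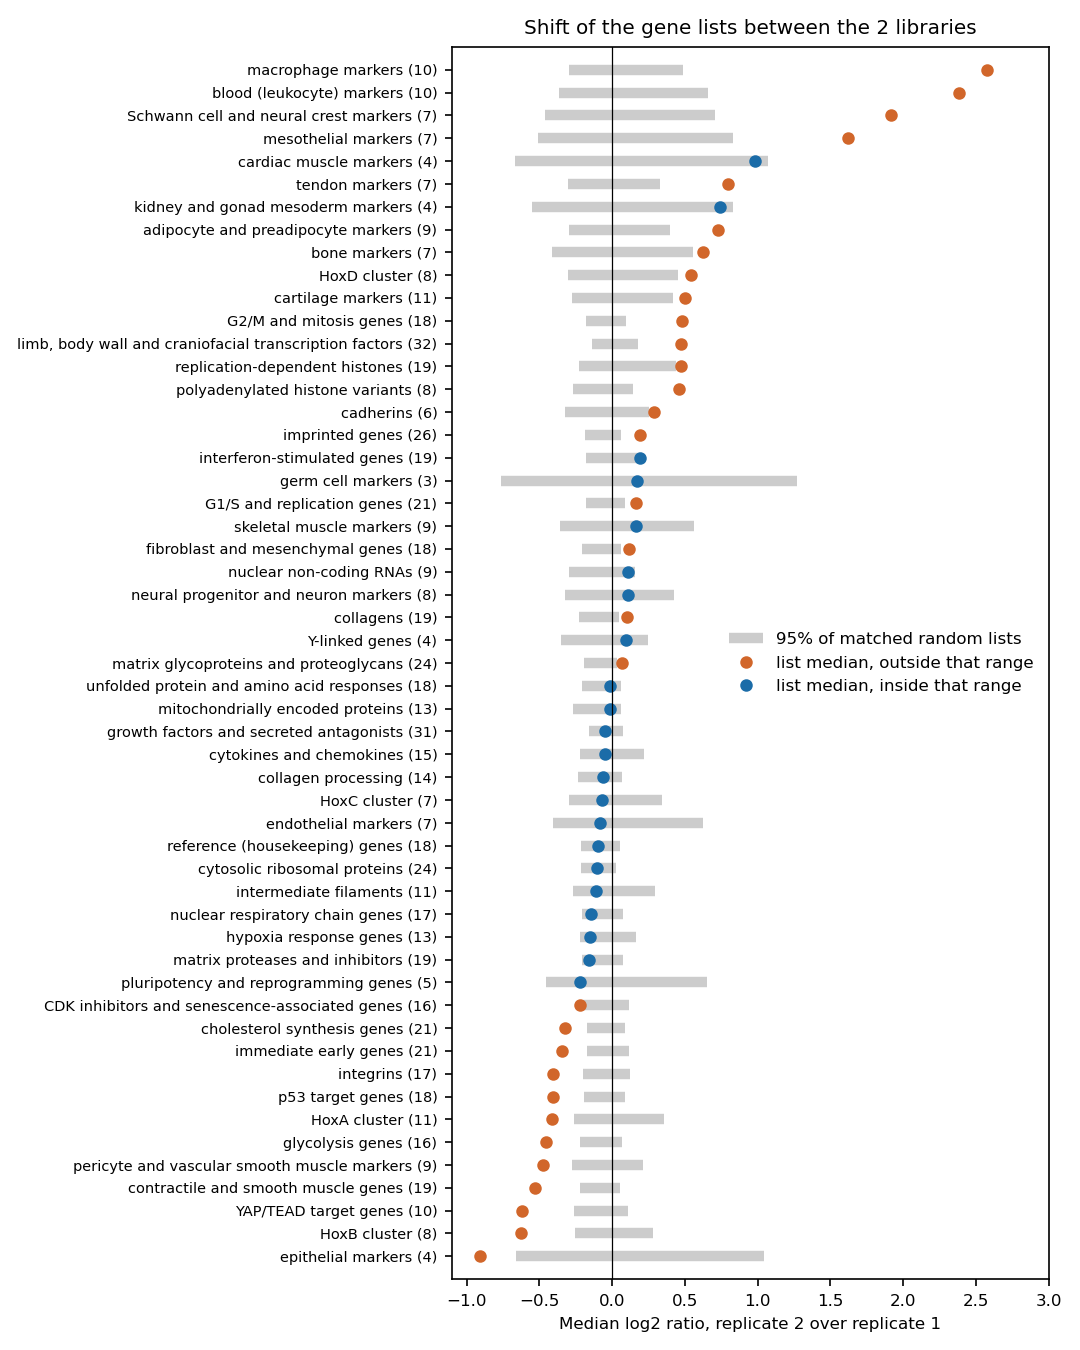
Points give the median log2 ratio of replicate 2 over replicate 1 for 53 fixed lists, with the number of genes tested in brackets, and grey bars span 95% of random lists matched on level. The macrophage (2.58) and leukocyte (2.38) medians are the highest, and the contractile (-0.53), YAP/TEAD (-0.62) and HoxB (-0.62) medians lie below their bars, whereas the bone, skeletal muscle and neural medians turn to -0.17, -0.20 and -0.24 over members with a mean TPM of at least 1.

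Expression of sex-linked genes went with the male label in both libraries, in that Y-linked genes were detected and Xist was not. Of 8 Y-linked genes 4 were detected, Eif2s3y at 57.2 ± 0.240, Ddx3y at 42.5 ± 2.09, Uty at 17.7 ± 2.48 and Kdm5d at 17.2 ± 0.658 TPM, and none differed between the libraries (median log2 ratio 0.10, percentile 85.5). Zfy1, Zfy2, Usp9y and the testis-determining gene Sry had 0 in both. Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254), stood at 0.155 ± 0.0354 TPM and its antisense partner Tsix at 0, so neither of these 2 X inactivation RNAs was detected.

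Transcript shares were alike in the 2 libraries for most of 26 genes with more than 1 transcript. Myl6 and Flnb, 2 of the 28 fixed genes, had a single transcript and are left out. The most abundant transcript was the same in both libraries for 24 of the 26, and it was an annotated protein-coding transcript in 19. It took over 50% of the gene's TPM in 6. The SD between the libraries had a median of 2.02 percentage points and a maximum of 9.97, for Eef1d. Pkm, the glycolytic pyruvate kinase gene, gave 69.5 ± 5.09% to Pkm-201 and 30.5 ± 5.09% to Pkm-202. Cdc42-202 took 98.5 ± 0.282%, Bin1-202 93.4 ± 2.04%, Tpm2-203 64.9 ± 1.83% and Actn1-202 56.0 ± 0.283%, and at Cdkn2a, which encodes p16 and p19, Cdkn2a-201 took 53.6 ± 2.49% and Cdkn2a-202 46.4 ± 2.49%. The leading Fn1 transcript, Fn1-205 with 28.0 ± 0.986%, was a 426-base model annotated for nonsense-mediated decay. Shares of TPM weight short models, and by expected counts 22 of the 26 shares moved by more than the spread between the libraries.

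The widest single-gene ratios were mainly in pseudogenes and small RNA genes. Among the 20 genes with the largest ratios, 10 in each direction, 17 had 0 counts in 1 library, 14 were processed pseudogenes, 4 were small RNA genes and 2 were protein-coding. Gm14414 (chromosome 2, 177460275 to 177460847) had 0 and 534 counts and was at least 174-fold higher in replicate 2, against a floor of 3 counts per library, and Cbx3-ps7 was at least 77.1-fold higher. Gm10020 (chromosome 15, 52477617 to 52478228) had 510 and 0 counts and was at least 174-fold lower, and Gm10123 with 927 and 11 counts was 86.3-fold lower. The protein-coding genes were Sowahc, at least 49.5-fold higher with 0 and 152 counts, and Gm10031, at least 66.9-fold lower with 196 and 0 counts. Gm26377 lay within Eef1a1. The 20 genes shared a median of 94.9% of their 36-base stretches with GENCODE M21 transcripts of other genes, so these values are uncertain. Gm10031 shared 92.2%. Sowahc shared 0%, but genes absent from GENCODE M21 were not searched.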

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

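The tests of a lower share of fibroblasts and of carried-over blood were chosen only after the result was seen. The design has 1 group, so no biological explanation was tested for any pattern here beyond which cells the libraries held.

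Entries outside the gene comparisons held reads. tRNA entries took 2485.44 expected counts in replicate 1 and 2990.06 in replicate 2, spread over 2184 and 2287 entries, so about 1 count each. Spike-in sequences took 6 and 12 counts, over 4 and 6 of 97 sequences, too few to tell whether any were added.

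Macrophage and leukocyte markers were higher in replicate 2, with list medians of 2.58 and 2.38 on the log2 scale. Carried-over blood that still held its red cells is argued against by the 5 haemoglobin genes, whose summed TPM was 0 in replicate 2, where Lyz2 stood at 61.3. White blood cells left without red cells are not excluded. For white cells of every kind, 10 further lymphoid genes were read. Of these 2, Lck and Trac, reached 0.5 TPM in replicate 2, while 6 had 0 counts in both libraries. Whether embryos of the labelled age hold cells with these genes is not given here, so their low levels do not decide on white cells in general. Lck and Trac stood at 1.70 and 0.900 TPM in replicate 1 and at 2.70 and 2.72 in replicate 2, with 33 and 12 counts there, so a few lymphoid cells are not excluded. A few macrophages among the cells of replicate 2 are a candidate explanation that stays open, since 10 further macrophage genes, not looked at before, had a median log2 ratio of 2.15 over the 6 tested (percentile 99.99 of random lists), and 8 of the 10 reached 0.5 TPM against 1 in replicate 1. These genes were low throughout, Ctss at 2.60 and Fcgr3 at 2.45 TPM in replicate 2.

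As lists, contractile, YAP/TEAD target and glycolysis genes lay lower and mitotic and imprinted genes higher in replicate 2. Their pooled medians differed by 0.94 on the log2 scale, a gap that follows in part from taking these lists for their direction. By the binomial test and the 2-fold rule, 1 contractile, 3 YAP/TEAD target and 0 glycolysis genes were lower, and 0 mitotic and 6 imprinted genes higher. GC content and length as the whole cause are argued against, because the difference was 0.87 (SD of resampled lists 0.0814) after their trend, which explained 1.44% of the variance over 13858 genes, was removed. That SD treats list members as independent, although genes move together. For a lower share of fibroblasts, the collagen median lay 0.63 above the contractile median, with a spread of 0.0957 for random lists. Both medians were known beforehand, and the contractile list was taken because it was low, so this gap does not decide on that share. The fibroblast genes did not fall as a list either, with a median of 0.12, 12 members above 0 and 6 below. Their summed TPM, however, was 5572 in replicate 1 and 4127 in replicate 2. A changed mix of mesenchymal and other cells was not tested and stays open, as pericyte markers were lower as a list (-0.47) and Schwann cell (1.92), mesothelial (1.62) and tendon (0.80) markers higher. The Schwann cell list was near the floor, at medians of 0.11 and 0.64 TPM in replicates 1 and 2, as was the mesothelial list, at 0.16 and 0.765. Each had 1 member detected. By edgeR's exact test 0 of the pericyte and tendon calls passed. Differences in culture density, passage or growth between the 2 cultures were not recorded in the labels and stay untested.

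The largest ratios lay in pseudogenes and small RNA genes with 0 or few counts in 1 library. Reads shared with near-identical transcripts remain a candidate explanation, since the 20 genes shared a median of 94.9% of their 36-base stretches with other genes, against 1.62% for 300 random genes and 62.7% for 200 random processed pseudogenes. Sowahc, with 0 and 152 counts, shared 0%, so the search gave no such account of it. The search covered GENCODE M21 transcripts, while the counts rest on GENCODE M4, so sharing with genes absent from M21 is not excluded.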

How the results depend on the processing

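The cause was not tested for any value given here unless one is stated. The restriction to protein-coding genes and the random lists of protein-coding genes were chosen only after the results were seen. With such random lists, the level percentile of the integrins was 71.4 instead of 95.2 and that of the intermediate filaments 4.86 instead of 35.3. Other lists fell further. The limb, body wall and craniofacial factors were at 4.73 instead of 61.6 and the replication-dependent histones at 17.3 instead of 67.9. The cytokines and chemokines were at 20.4 instead of 70.0 and the interferon-stimulated genes at 41.6 instead of 85.1. The number of genes detected stayed within 1.5 times 13615 under every alternative, from 12818 with FPKM to 18511 at 0.1 TPM. All 53 list shifts kept their direction and side with RLE factors. The 25 highest genes held 28.0% of expected counts and 30.2% of posterior mean TPM, and 30.9 to 34.4% with each replicate left out. The correlation of 0.985 was 0.969 with a pseudocount of 0.1, 0.976 over detected genes, 0.990 with posterior means and 0.988 with log2 CPM. The coefficient of variation was 0.225 without a filter, where 24413 genes entered, and 0.181 at a mean TPM of at least 10.

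Against 1160 genes differing (745 higher, 415 lower), ratios of TPM + 1 gave 590 (357 higher, 233 lower), a 1.5-fold limit 2123 (1200 and 923) and edgeR's exact test with the pair's own dispersion 357 (257 and 100), all 357 among the 1160. At a mean TPM of at least 1, 453 were higher, and over protein-coding genes alone 265 were lower, both from fewer genes tested. With a replicate left out no difference can be computed.

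With ratios of TPM + 1, list shifts were 0.059 for cadherins, -0.17 for CDK inhibitors, 0.27 for HoxD, 0.25 for cartilage and 0.24 for bone, all 5 then inside the random range, and -0.20 for cytokines and 0.65 for kidney and gonad, both then outside it, and 0.46 for cardiac muscle. The endothelial (0.01) and skeletal muscle (-0.03) shifts changed sign with them. Over members with a mean TPM of at least 1, they were -0.44 for intermediate filaments, -0.32 for HoxC and 0.27 for nuclear non-coding RNAs, all 3 then outside the random range, and -0.13 for growth factors. The shifts of the neural (0.11), skeletal muscle (0.16) and bone (0.63) markers reversed there, to -0.24, -0.20 and -0.17. Not every list was recomputed over those members.

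Markers detected rose from 1 to 2 (epithelial), 1 to 4 (leukocyte), 2 to 6 (macrophage), 0 to 1 (erythroid), 1 to 3 (Schwann cell), 0 to 2 (liver), 1 to 3 (mesothelial) and 1 to 2 (germ cell) at 0.5 TPM. At 10 counts in both libraries they were 2, 2, 7, 1 and 3 for the first 5, 3 for mesothelial, 2 for germ cell and 8, not 5, for cartilage. Posterior means gave 7 leukocyte, 2 erythroid, 2 Schwann cell and 2 liver markers, and TPM without mitochondrial genes 2 Schwann cell markers. Leaving out each replicate gave 1 to 2 epithelial, 1 to 8 leukocyte, 2 to 10 macrophage, 0 to 1 erythroid, 2 to 3 Schwann cell and 1 to 2 mesothelial markers. Without replicate 1, the leukocyte and macrophage counts were 8 and 10.

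Among single genes, the mean TPM moved by more than 1 SD in 158 of 435 with posterior means and in 83 of 419 without mitochondrial genes, and 22 of 26 transcript shares moved with expected counts. The median TPM of a list moved by more than 1 SD in 19 of 57 lists with posterior means, in 15 of 56 without mitochondrial genes, in 11 of 57 without replicate 1 and in 15 of 57 without replicate 2. A TPM from few counts limits the cell type lists, and 2 libraries limit every SD.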

Other observations

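Other genes that differed between the libraries lay outside the fixed lists, and all genes in this paragraph were chosen after their values were seen. Higher in replicate 2 were Igfbp5, which binds insulin-like growth factors, at 84.2 and 405 TPM in replicates 1 and 2, and the matricellular gene Ccn3 at 13.99 and 89.4 TPM. So were the growth factor midkine, Mdk, at 14.7 and 70.4 TPM, the angiotensin receptor gene Agtr2 at 7.63 and 53.1 TPM and Egfl6 at 3.2 and 29.9 TPM. The small leucine-rich repeat proteoglycan genes Aspn and Ogn stood at 69.5 and 51.3 TPM in replicate 1 against 200.4 and 145 TPM in replicate 2. The hedgehog co-receptor genes Gas1 and Cdon stood at 39.4 and 21.6 TPM in replicate 1 against 123 and 64.4 TPM in replicate 2. Lower in replicate 2 were Ptgs2, which encodes the inducible cyclooxygenase, at 156 and 47.4 TPM, the small heat shock gene Hspb1 at 179 and 63.1 TPM, the chromatin gene Hmga2 at 229 and 97.8 TPM, the lysyl oxidase Loxl3 at 174 and 77.5 TPM and the urokinase receptor gene Plaur at 31.5 and 13.7 TPM. All of these but Hmga2, Loxl3 and Plaur also passed edgeR's exact test at an adjusted p under 0.05.

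Several of the most abundant entries had little sequence of their own. Of the 36-base stretches of Gm42418, 95.8% occurred in GENCODE M21 transcripts of other genes. The same held for 100% of those of mt-Co2, 99.9% of those of mt-Co3 and 59.7% of those of mt-Co1. The entries mt-Rnr1, mt-Ts1 and Mir6236 shared 0%, but entries absent from M21, such as ENSMUSG00000045999.9, were not searched. Snord14c and Snord14d shared 100%, with Hspa8 as the closest gene, and Rpl39-ps shared 69.0% with Rpl39 as the closest. Among long non-coding RNAs outside the fixed lists, Snhg12 stood at 94.6 and 123 TPM, Snhg6 at 69.5 and 79.1 TPM and Pvt1 at 37.7 and 34.9 TPM, and none of these 3 differed between the libraries. They too were chosen after their values were seen.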
